A study of Arabidopsis thaliana with 24 samples.

How the data were processed

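RNA-seq was made from roots and shoots of Arabidopsis Col-0 plants given 50 µl of Penicillium sp. D7 inoculum or water, on medium with 15 µM arsenite or none. Plants grew for 7 days before and 7 days after inoculation, and 8 groups of 3 libraries gave 24 libraries. The labels call the replicates biological but do not state their separate origin, so p-values measure the spread between these samples. The deposited values are FPKM per gene and library, computed by the authors per the labels. Per the submitters' processing notes, reads were converted with CASAVA, aligned with HISAT2 2.0.5 to TAIR10 and counted with HTSeq 0.6.1. The labels name a NEBNext Ultra RNA kit, which does not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be separated. Near-identical copies, among them LHCB1, RBCS, PDF1.2, the small heat shock proteins, GSTF6 and GSTF7, and PHT1;1, PHT1;2 and PHT1;3, are uncertain 1 by 1.

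The file lists 32833 genes by AGI code, 32548 of them in the reference annotation, and codes are used in place of coordinates. No libraries were identical. Each value multiplied by the exonic length of its gene is a whole multiple of 1 step per library. At a tolerance of 0.05 reads, 99.2% to 99.4% of values up to 200 reads were whole, and reads of 32429 genes (98.8%) were recovered. They sum to 14.7 to 25.5 M per library. The steps correspond to a denominator of 15.3 to 29.8 M per library, which is 0.831 to 1.2 times that sum. Over the 24 libraries the denominators lie within 0.16% of median-of-ratios factors, taken from the reads of 18550 genes above 0 in every library. The origin of the denominators is not given in the sources used here. Intervals and floors cover counting error only.

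Comparisons, tests, 29 gene lists, the panel of 18 genes, the rule for naming genes and the alternatives, except those named below as added, were set before the data were examined. Within each tissue, limma 3.58.1 in R 4.3.3 fitted 4 group means to log2(FPKM + 1) with a mean-variance trend, for genes at 1 FPKM or more in at least 3 libraries. The 5 comparisons per tissue were tested at a Benjamini-Hochberg adjusted p of 0.05. There were 19385 root genes and 18572 shoot genes tested, 19270 and 18370 without the 2 libraries that go against their tissue label. Differences between tissues used 8 group means on 17277 genes, or 16989. The fit without the 2 libraries was added after the data had been seen. Gene lists with 3 or more tested members (29 in roots, 28 in shoots) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, over 540 genes whose codes were checked against the annotation. All 29 are named under arsenite in mock roots.

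Genes are named by a rule: the 5 largest rises and 5 largest falls of a comparison among called genes with a symbol, a mean of 5 FPKM or more in 1 group and no overlap between libraries; the largest called members of each list with 3 or more called; and the panel whatever its result. For arsenite in D7 plants and for interactions the text shortens the first parts, in order of size. After the first comparison, other panel genes are a range. Expected overlaps are n1 × n2 / N per direction, and comparisons with shared libraries were set beside 100 simulated sets of unchanged groups.

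With 200 simulated changes, the fit without the 2 libraries called 62.9% of 2-fold and 95.9% of 4-fold ones for arsenite in mock roots. It called 56.6% and 89% in mock shoots and 33% and 88.9% for the root interaction. Where real groups vary more, the shares fall. Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a filter of 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, no trend, a 2-fold minimum, only the groups compared, the replicate number as a block and each library left out in turn. Added after the data were seen were voom on recovered reads and fits without the 2 libraries, alone and with D7 arsenite shoot 1. The replicate numbers carried a shared deviation only for arsenite in D7-inoculated roots (correlations of 0.155, 0.122 and 0.222), where a replicate block gave 3597 genes, or 0 by limma with all libraries. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.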

Results

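Seedlings of Arabidopsis thaliana, accession Col-0, were grown with water or with spores of Penicillium sp. strain D7, a filamentous fungus, and with or without 15 µM arsenite, the trivalent inorganic form of arsenic. Polyadenylated RNA of roots and of shoots was sequenced after 7 days with the fungus. The 8 groups were mock control, mock arsenite, D7 control and D7 arsenite in each tissue, 3 libraries each and 24 in all. Recovered reads summed to 14.7 to 25.5 M per library, and 3 reads on a 1 kb transcript corresponded to 0.101 to 0.195 FPKM. The comparisons ask what arsenite changed with and without the fungus, what the fungus changed with and without arsenite, and whether its effect depended on arsenite.

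Of the 24 libraries, 2 went against their tissue label. The library labelled mock arsenite root 3 held 16391 FPKM of LHCB1.3, a light-harvesting protein of leaves, where the other mock arsenite root libraries held 141 and 178 FPKM. Its median over the photosynthesis genes was 2494 FPKM against 13.1 and 19.7 FPKM, and its median over root cell type markers was 0.872 FPKM against 27.3 and 28.4 FPKM. The library labelled mock arsenite shoot 3 showed the opposite, with 206 FPKM of LHCB1.3 against 20842 and 20747 FPKM, and a root marker median of 33.6 FPKM against 0.165 and 0.085 FPKM. A smaller departure was seen in the library labelled D7 arsenite shoot 1, which had a root marker median of 1.62 FPKM against 0.22 and 0 FPKM in its group, and 5.35 FPKM of CASP1, a protein of the root endodermis, against 0.721 and 0 FPKM.

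**Figure D1:**
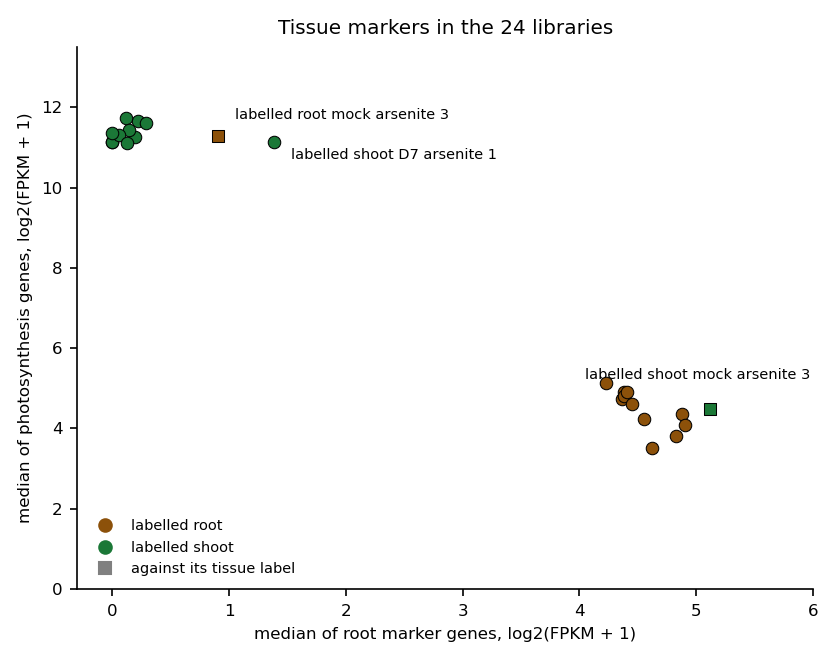
Median of the photosynthesis genes (vertical) against that of the root cell type markers (horizontal), as log2(FPKM + 1), 1 point per library, coloured by labelled tissue. The library labelled mock arsenite root 3 lies among the shoot libraries at 2494 FPKM, and the library labelled mock arsenite shoot 3 among the root libraries at 21.6 FPKM.

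Each comparison was therefore fitted on all 12 libraries of a tissue, as planned, and again without these 2 libraries, which leaves n = 2 for mock arsenite. The genes and groups below are described from the fit without the 2 libraries, a choice made after the data had been seen, and no library was moved to another group. Levels are means ± SD in FPKM, n = 3 or, for mock arsenite, n = 2. A log2 change is the limma estimate on log2(FPKM + 1) ± its standard error, with the Benjamini-Hochberg adjusted p over all genes tested. Values after a symbol are log2 changes. In gene lists, up and down are counts past the threshold over all genes tested. The adjusted p of a list is from camera with its preset correlation, followed by that with an estimated correlation. Between the 2 fits no gene passed in opposite directions within a tissue. A 2-fold minimum left 63 to 1126 genes per comparison, each count over 1.5 times lower.

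**Figure D2:**
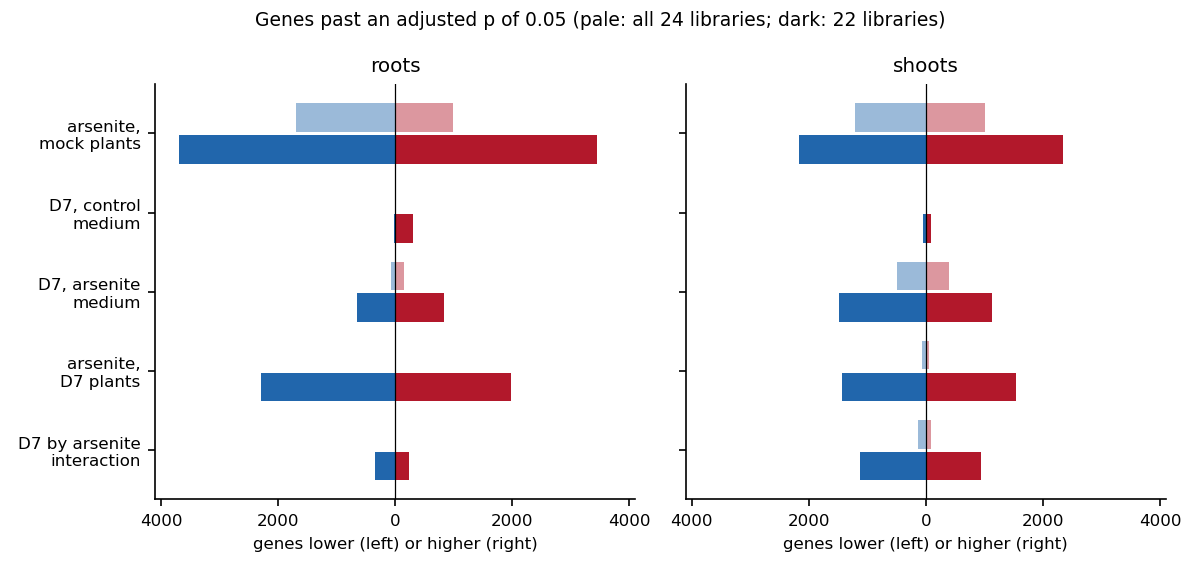
Genes past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left, on all libraries (pale) and without the 2 libraries that go against their tissue label (dark). In mock roots under arsenite 2681 genes passed on all libraries and 7146 without the 2.

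In roots without the fungus, arsenite raised 17 of 27 sulfate and 14 of 19 nitrogen uptake and assimilation genes, 11 of 19 indole glucosinolate and camalexin and 9 of 10 flavonoid genes, and 21 of 29 glutathione transferases, and lowered 13 of 19 PIP and TIP aquaporins and 10 of 11 aliphatic glucosinolate genes. None of these lists passed camera with an estimated correlation (adjusted p = 0.15 to 0.218). CYP71A12, a cytochrome P450 of camalexin and indole nitrile synthesis, rose from 1.1 ± 0.258 to 74.2 ± 11.4 FPKM (5.16 ± 0.13, adjusted p = 8.1e-09). The high-affinity nitrate transporters NRT2.2 and NRT2.4 rose from 1.07 ± 0.303 to 46.3 ± 1.01 FPKM (4.52 ± 0.28, adjusted p = 2.6e-06) and by 4.04 ± 0.17. SDI1 and LSU1, markers of sulfur deficiency, rose from 1.14 ± 0.093 to 33.8 ± 12.0 FPKM (3.98 ± 0.19, adjusted p = 5.3e-07) and by 3.59 ± 0.32. The largest fall was in TIP2;3, a tonoplast aquaporin, from 229.5 ± 20.6 to 22.3 ± 2.17 FPKM (−3.31 ± 0.2, adjusted p = 2.4e-06). It was followed by the sucrose exporter SWEET12, from 26.8 ± 4.69 to 2.08 ± 0.311 FPKM (−3.17 ± 0.38, adjusted p = 0.00016), and by UMAMIT20, SNG1, a sinapoyltransferase, and scpl2 (AT1G73300), a carboxypeptidase-like protein, with log2 changes of −2.88 ± 0.31, −2.86 ± 0.3 and −2.69 ± 0.27.

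Among the glutathione transferases, 21 of 29 genes rose and 0 fell, 21 adjusted over the list alone, led by GSTF7 2.56, GSTF6 2.55 and GSTU12 2.41 (adjusted p = 5.19e-08, 0.15 with an estimated correlation). Of the sulfate genes, 17 of 27 genes rose and 4 fell, 23 adjusted over the list alone (adjusted p = 7.75e-05, 0.15 with an estimated correlation), and beside SDI1 and LSU1 the vascular sulfate transporter SULTR2;1 rose by 2.78 ± 0.14. Thiol and arsenic detoxification had 4 up and 1 down of 10, 6 adjusted over the list alone, with GGCT2;1 3.16 and GR1 0.76 (adjusted p = 0.0419, 0.205 with an estimated correlation). GGCT2;1 recycles glutamate from glutathione and GR1 is a glutathione reductase. Phosphate starvation genes split, as 13 of 24 genes rose and 3 fell, 17 adjusted over the list alone, led by PS2 1.85 and SPX3 1.83 (adjusted p = 0.000325, 0.15 with an estimated correlation). In the NIP aquaporins, some of which carry arsenite, 3 of 5 genes rose and 1 fell, 4 adjusted over the list alone, with NIP1;1 1.41 and NIP3;1 −0.86 (adjusted p = 0.355). Of the PIP and TIP aquaporins, 3 of 19 genes rose and 13 fell, 16 adjusted over the list alone, and PIP2;3, a plasma membrane water channel, changed by −2.45 ± 0.14 (adjusted p = 9.38e-06, 0.213 with an estimated correlation).

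Heat shock and folding genes (9 up and 2 down of 18, 11 adjusted over the list alone) were led by HSP23.5 2.79 and HSP90.1 1.55 (adjusted p = 0.0144, 0.205 with an estimated correlation). Unfolded protein response genes of the endoplasmic reticulum had 11 up and 0 down of 13, 11 adjusted over the list alone, with PDIL1-2 1.21 and BIP2 1.19 (adjusted p = 5.44e-06, 0.205 with an estimated correlation). Oxidative stress genes went both ways, 6 up and 5 down of 23, 11 adjusted over the list alone, with UPOX 2.27 and GPX1 −1.17 (adjusted p = 0.508). Indole glucosinolate and camalexin genes (11 up and 1 down of 19, 12 adjusted over the list alone) included, after CYP71A12, CYP82C2 of the indole nitrile branch at 3.08 ± 0.28 (adjusted p = 2.42e-05, 0.205 with an estimated correlation). Aliphatic glucosinolate genes fell, 1 up and 10 down of 11, 11 adjusted over the list alone, led by the chain-elongation synthases MAM1 −2.3 and MAM3 −2.05 (adjusted p = 2.04e-06, 0.205 with an estimated correlation). Phenylpropanoid and lignin genes (14 up and 0 down of 16, 14 adjusted over the list alone) were led by 4CL3 2.6 and 4CL1 1.93 (adjusted p = 6.98e-11, 0.205 with an estimated correlation). Flavonoid and anthocyanin genes (9 up and 1 down of 10, 10 adjusted over the list alone) rose most in DFR 3.33 and LDOX 2.9, the late anthocyanin enzymes (adjusted p = 5.44e-06, 0.213 with an estimated correlation). Nitrogen genes had 14 up and 1 down of 19, 15 adjusted over the list alone (adjusted p = 1.01e-05, 0.218 with an estimated correlation).

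Salicylate and systemic resistance genes (8 up and 1 down of 18, 10 adjusted over the list alone) were led by FMO1 2.36 and GRXC9 2.35 (adjusted p = 0.0021, 0.407 with an estimated correlation). Jasmonate genes (5 up and 0 down of 18, 4 adjusted over the list alone) were led by TAT3 2.33 and JAZ10 1.85 (adjusted p = 0.0136, 0.499 with an estimated correlation). Iron deficiency and coumarin genes (10 up and 1 down of 20, 11 adjusted over the list alone) were led by S8H 1.99 and F6'H1 1.89 (adjusted p = 0.0144, 0.355 with an estimated correlation). Photosynthesis genes had 2 up and 12 down of 22, 15 adjusted over the list alone, led by LHCA4 −1.58 and LHCA1 −1.31 (adjusted p = 0.00227, 0.534 with an estimated correlation). Root cell type markers had 6 up and 1 down of 12, 8 adjusted over the list alone, led by PRP3 1.43 and LRX1 1.21 (adjusted p = 0.00679, 0.205 with an estimated correlation). Suberin genes had 7 up and 1 down of 14, 8 adjusted over the list alone, with FAR5 1.08 and CYP86B1 0.69 (adjusted p = 0.00198, 0.218 with an estimated correlation). Expansins had 6 up and 1 down of 9, 8 adjusted over the list alone, with EXPA15 2.75 and EXPA1 2.35 (adjusted p = 0.00274, 0.22 with an estimated correlation). Cell cycle genes had 8 up and 1 down of 18, 9 adjusted over the list alone, with CYCD3;1 1.02 and PCNA1 0.72 (adjusted p = 0.00227, 0.396 with an estimated correlation). Lists not past camera held WRKY29 −1.19 and PER4 0.73 in pattern-triggered immunity (2 up and 1 down of 20, 3 adjusted over the list alone), ERF104 −1.6 and ERF1 1.22 in ethylene and defensins (2 up and 8 down of 14, 11 adjusted over the list alone), and IAA5 1.09 and PIN7 0.85 in auxin (4 up and 3 down of 21, 6 adjusted over the list alone). They also held RD29B −2.41 and RAB18 −1.81 in abscisic acid and dehydration (0 up and 5 down of 16, 5 adjusted over the list alone), SWEET12 and SWEET14 (1.76 ± 0.21) in sugar transport (3 up and 7 down of 12, 10 adjusted over the list alone), and SAG13 2.71 and DIN1 −1.75 in senescence and carbon starvation (2 up and 3 down of 8, 5 adjusted over the list alone). Of the ferritins, 1 of 4 genes fell and 0 rose, 1 adjusted over the list alone. The camera adjusted p of these 7 lists ranged from 0.073 to 0.807.

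From the panel of 18 genes fixed beforehand, NIP1;1, an aquaglyceroporin that carries arsenite, rose from 55.9 ± 4.01 to 151 ± 14.1 FPKM (1.41 ± 0.18, adjusted p = 0.00025), and ABCC2, a vacuolar transporter of phytochelatin-bound arsenic, from 26.2 ± 1.62 to 42.5 ± 1.31 FPKM (0.68 ± 0.09, adjusted p = 0.00028). UPOX (AT2G21640), a marker of oxidative stress, changed by 2.27 ± 0.16, PAD3, the last enzyme of camalexin synthesis, by 2.44 ± 0.16, CHS, chalcone synthase, by 2.46 ± 0.42, and GSTU24 by 1.59 ± 0.12. The sulfate reduction and uptake genes APR3 and SULTR1;1 changed by 1.09 ± 0.08 and 2.11 ± 0.18, the disaggregase HSP101 by 0.47 ± 0.11 and the phosphate transporter PHT1;1 by −0.51 ± 0.13. Not past the threshold were PCS1 0.58, HAC1 −0.09, ABCC1 0.23, GSH1 0.04, FRK1 −0.13, IRT1 0.81. Adjusted p was 0.058 to 0.65. PR1 and PDF1.2A were listed at 0 FPKM in all 11 root libraries and were not tested.

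Here 7146 genes passed without the 2 libraries, 3446 higher and 3700 lower. As planned the count was 2681, 984 higher and 1697 lower. Among genes tested in both fits, 2652 of 2654 planned calls also passed without the 2 libraries in the same direction. The count was 392 as planned with only the groups compared, and 4671 without mock arsenite root 2. Among the genes named here, GRXC9, JAZ10, S8H, PCNA1, PER4, ERF1, IAA5, RAB18 and PHT1;1 missed the threshold without 1 or more of mock arsenite 1 and 2 and mock control 1, 2 and 3 (adjusted p up to 0.157). In the panel the highest was 0.0694 for PHT1;1 without mock arsenite 1. GRXC9, JAZ10 and ERF104 were 1.51, 1.09 and −2.35 without mock arsenite 1 and 3.19, 2.62 and −0.84 without 2.

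In control roots, D7 raised 7 of 19 indole glucosinolate and camalexin genes, 14 adjusted over the list alone, and 11 of 29 glutathione transferases, 15 adjusted over the list alone. Both lists passed camera (adjusted p = 1.48e-17 and adjusted p = 1.38e-16), also with an estimated correlation (adjusted p = 0.0476 each). CYP71A12 rose from 1.1 ± 0.258 to 87.8 ± 12.2 FPKM (5.4 ± 0.12, adjusted p = 1.4e-09). CYP82C2 rose from 0.641 ± 0.745 to 36.2 ± 5.94 FPKM (4.58 ± 0.25, adjusted p = 1.5e-06). The phi-class glutathione transferases GSTF7 and GSTF6, which share most of their sequence, rose from 23.9 ± 2.5 to 255 ± 49.9 FPKM (3.35 ± 0.14, adjusted p = 4.8e-07) and by 3.21 ± 0.16, and CYP81F2, which hydroxylates indole glucosinolates, rose by 3.2 ± 0.17. Only 15 genes fell. The falls were led by RD29B, a dehydration-responsive gene, from 10.8 ± 3.02 to 2.43 ± 1.1 FPKM (−1.81 ± 0.29, adjusted p = 0.0081), and by the subtilase SBT4.12, CYP71B26, NAC074 and NYE1, with log2 changes of −0.56 ± 0.08, −0.53 ± 0.11, −0.51 ± 0.1 and −0.45 ± 0.09.

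IGMT2, which methylates indole glucosinolates, and GSTF3 rose by 2.61 ± 0.32 and 1.97 ± 0.24. Salicylate genes (4 up and 0 down of 18, 11 adjusted over the list alone) included the salicylate regulator CBP60G 2.06 and FMO1 0.88 (adjusted p = 9.65e-11, 0.28 with an estimated correlation). Pattern-triggered immunity (3 up and 0 down of 20, 6 adjusted over the list alone) was led by the peroxidases PER4 1.65 and PER5 0.85 (adjusted p = 1.04e-06, 0.48 with an estimated correlation). Phosphate starvation genes (3 up and 0 down of 24, 7 adjusted over the list alone) rose in PHT1;3 2.23 and PHT1;2 1.01 (adjusted p = 0.000195, 0.114 with an estimated correlation). From the panel, PAD3 rose from 2.58 ± 0.672 to 16.1 ± 3.13 FPKM (2.25 ± 0.15, adjusted p = 8.2e-06), and GSTU24 and APR3 changed by 0.92 ± 0.11 and 0.47 ± 0.08. In the panel 13 did not pass (−1.17 to 0.56, adjusted p = 0.19 to 0.99).

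The count was 318 without the 2 libraries, 303 higher and 15 lower. As planned it was 15, all higher. Neither of the 2 libraries belongs to the groups compared, but on all libraries the shared spread includes mock arsenite root 3. It was 478 with only the groups compared, 175 without D7 control root 3, 208 without mock control root 1 and 205 without mock control root 2. In the leave-one-out fits, CYP71B26, NAC074, NYE1, PER5 and APR3 missed the threshold without 1 or more of D7 control 1, 2 and 3 and mock control 1, 2 and 3 (adjusted p up to 0.172). The panel maximum was 0.0523 for APR3 without D7 control 3.

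In roots under arsenite, D7 lowered 10 of 27 sulfate, 12 of 16 phenylpropanoid and 6 of 10 flavonoid genes and raised 9 of 11 aliphatic glucosinolate genes and 6 of 19 PIP and TIP aquaporins. With an estimated correlation these lists did not pass (adjusted p = 0.129 to 0.469). PHT1;3, a phosphate transporter with near-identical copies, rose from 0.155 ± 0.182 to 11.9 ± 1.36 FPKM (3.48 ± 0.17, adjusted p = 1.6e-06). PIRL8 (AT4G26050), a leucine-rich repeat protein, and CCOAMT (AT1G67980), a caffeoyl-CoA methyltransferase, rose by 2.34 ± 0.18 and 2.33 ± 0.28, and the expansin EXPA12 and the salicylate regulator CBP60G changed by 2.3 ± 0.35 and 1.97 ± 0.27. EARLI1 (AT4G12480), a lipid transfer-like protein, fell from 21.3 ± 3.6 to 1.27 ± 0.698 FPKM (−3.34 ± 0.27, adjusted p = 4.6e-05). UMAMIT19 and the organic cation transporter OCT1 (AT1G73220) changed by −3.0 ± 0.23 and −2.57 ± 0.21. NRT2.4 and NRT2.2 changed by −2.48 ± 0.17 and −2.44 ± 0.28.

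Of the phenylpropanoid genes, 12 of 16 genes fell and 0 rose, 14 adjusted over the list alone, led by 4CL3 −1.29 and F5H1 −1.04 (adjusted p = 1.56e-14, 0.132 with an estimated correlation). Of the flavonoid genes, 1 of 10 genes rose and 6 fell, 9 adjusted over the list alone, led by DFR −2.42 and LDOX −2.3 (adjusted p = 3.9e-06, 0.469 with an estimated correlation). Sulfate genes (2 up and 10 down of 27, 19 adjusted over the list alone) was led by SDI1 −2.29 and SULTR2;1 −2.03 (adjusted p = 0.000163, 0.129 with an estimated correlation). Heat shock genes (0 up and 6 down of 18, 7 adjusted over the list alone) was led by HSP23.5 −1.88 and HSP70 −1.55 (adjusted p = 0.000372, 0.129 with an estimated correlation). Aliphatic glucosinolate genes (9 up and 0 down of 11, 9 adjusted over the list alone) rose, with MAM1 1.06 and CYP79F2 1.0 (adjusted p = 2.46e-10, 0.132 with an estimated correlation). Indole glucosinolate genes (8 up and 0 down of 19, 8 adjusted over the list alone) were led by the methyltransferase IGMT1 and by CYP81F2, at 1.74 ± 0.31 and 1.66 ± 0.2 (adjusted p = 0.000552, 0.469 with an estimated correlation). Pattern-triggered immunity (7 up and 0 down of 20, 7 adjusted over the list alone) was led by PER4 1.78 and PER5 1.6 (adjusted p = 0.000372, 0.519 with an estimated correlation). Of the PIP and TIP aquaporins, 6 of 19 genes rose and 1 fell, 10 adjusted over the list alone, with TIP2;3 1.5 and TIP2;2 0.92 (adjusted p = 0.000225, 0.469 with an estimated correlation).

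Nitrogen genes (1 up and 3 down of 19, 6 adjusted over the list alone) held, beside the nitrate transporters, the nitrate reductase NIA1 at 1.42 ± 0.23 (adjusted p = 0.00703, 0.519 with an estimated correlation). Iron deficiency genes (4 up and 1 down of 20, 7 adjusted over the list alone) were led by IMA2 0.79 and IRT2 −0.78 (adjusted p = 0.00535, 0.469 with an estimated correlation). Root cell type markers (0 up and 3 down of 12, 3 adjusted over the list alone) were led by PRP3 −0.89 and PRP1 −0.63 (adjusted p = 0.0498, 0.469 with an estimated correlation). Phosphate starvation genes went both ways (5 up and 5 down of 24, 13 adjusted over the list alone), with PHT1;3 and PHT1;2 (1.95 ± 0.17) rising and the ribonuclease RNS1 falling (−1.92 ± 0.31). Other lists not past camera were glutathione transferases (4 up and 5 down of 29, 14 adjusted over the list alone, with GSTU3 −1.68 and GSTF7 1.34), thiol and arsenic detoxification (1 up and 2 down of 10, 3 adjusted over the list alone, with GGCT2;1 −1.62 and HAC1 0.6), oxidative stress (2 up and 2 down of 23, 5 adjusted over the list alone, with UPOX −1.33 and FSD1 −0.86). So were ethylene and defensins (2 up and 2 down of 14, 4 adjusted over the list alone, with ACS7 −1.2 and HEL 0.72), sugar transport (3 up and 3 down of 12, 6 adjusted over the list alone, with SWEET13 −1.42 and SWEET14 −1.3) and expansins (2 up and 1 down of 9, 6 adjusted over the list alone, with EXPA8 −1.31 and EXPA14 1.08). Their camera adjusted p, with phosphate starvation included, ranged from 0.262 to 0.794.

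From the panel, PHT1;1 rose from 110.4 ± 5.66 to 239.8 ± 31.8 FPKM (1.1 ± 0.13, adjusted p = 0.00043), HAC1 (AT2G21045), an arsenate reductase, from 96.1 ± 4.36 to 146 ± 12.0 FPKM (0.6 ± 0.09, adjusted p = 0.0017), and UPOX fell from 17.2 ± 1.35 to 6.23 ± 0.583 FPKM (−1.33 ± 0.16, adjusted p = 0.00038). The pattern-response kinase FRK1, PAD3, SULTR1;1 and HSP101 changed by 0.63 ± 0.14, 0.62 ± 0.16, −0.81 ± 0.18 and −0.52 ± 0.11. In the panel 9 did not pass (−1.13 to 0.52, adjusted p = 0.068 to 0.93). Here 1492 genes passed without the 2 libraries, 837 higher and 655 lower. On all libraries the count was 210, 144 higher and 66 lower. With only the groups compared it was 546, and 1 (PHT1;3) as planned. It was 945 without mock arsenite root 1 and 756 without mock arsenite root 2. Of these genes, IGMT1, IMA2, PRP3, GGCT2;1, ACS7, HEL, EXPA14, FRK1, PAD3, SULTR1;1 and HSP101 missed the threshold without 1 or more of D7 arsenite 1, 2 and 3 and mock arsenite 1 and 2 (adjusted p up to 0.277). Panel maxima were 0.134 for FRK1 without mock arsenite 2, 0.171 for PAD3 without mock arsenite 1, 0.17 for SULTR1;1 without mock arsenite 1 and 0.0896 for HSP101 without mock arsenite 1.

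In D7-inoculated roots, arsenite raised 11 of 20 iron deficiency and coumarin genes, 14 adjusted over the list alone (adjusted p = 3.85e-07, 0.199 with an estimated correlation). In sugar transport, 1 of 12 genes rose and 7 fell, 8 adjusted over the list alone (adjusted p = 0.00534, 0.283 with an estimated correlation). IRT1, the root iron transporter, rose from 7.47 ± 7.98 to 38.4 ± 18.5 FPKM (2.5 ± 0.54, adjusted p = 0.011), and the microRNA gene MIR775 and the ferric reductase FRO2 by 2.28 ± 0.35 and 2.16 ± 0.49. LEA7, a late embryogenesis protein, SWEET12 and MRN1, marneral synthase, fell, with log2 changes of −2.48 ± 0.44, −2.31 ± 0.34 and −2.31 ± 0.17. Phosphate starvation had 10 up and 0 down of 24, 10 adjusted over the list alone (adjusted p = 1.23e-06, 0.0973 with an estimated correlation). Photosynthesis had 0 up and 15 down of 22, 20 adjusted over the list alone (adjusted p = 8.83e-10, 0.283 with an estimated correlation). From the panel, NIP1;1 rose from 53.2 ± 8.72 to 126 ± 28.8 FPKM (1.21 ± 0.16, adjusted p = 0.002), and APR3 0.57, SULTR1;1 1.31, UPOX 0.81, PAD3 0.81, FRK1 0.53 and HAC1 0.3 also passed. In the panel 8 did not (−0.17 to 0.99, adjusted p = 0.061 to 0.93).

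Here 4271 genes passed without the 2 libraries, 1971 higher and 2300 lower. As planned it was 3, and 2933 had an unadjusted p under 0.05. With the replicate number as a block it was 0 by limma, with 2727 at an unadjusted p under 0.05, where voom called 14 without the block. The 3, named after their values were seen, are AT2G43620, higher, and AGL71 and AT5G60060, lower. Planned splits were 1 higher and 1 lower when rescaled to a common total or scaled by median-of-ratios, and 2 and 1 after quantile normalization. Without the 2 libraries, rescaling gave 2912 higher and 1551 lower. The count was 2460 with only the groups compared in either fit, 1856 without D7 arsenite root 1, 1930 without D7 arsenite root 2, 1916 without D7 control root 1 and 2109 without D7 control root 3. By leave-one-out, FRO2, FRK1 and HAC1 missed the threshold without 1 or more of D7 arsenite 1 and 2 and D7 control 1 and 3 (adjusted p up to 0.0866). The panel reached 0.0505 for FRK1 without D7 control 3 and 0.0866 for HAC1 without D7 control 3. IRT1 and FRO2 were 3.23 and 2.79 without D7 control root 2.

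The difference between the effect of D7 under arsenite and its effect in control roots was tested as an interaction, where a negative value is a smaller rise or a larger fall under arsenite. CYP71A12 and CYP82C2, which D7 raised in control roots, had negative values (−4.44 ± 0.18, adjusted p = 1e-06, and −3.49 ± 0.37), as did the tyrosine aminotransferase TAT3 (−3.0 ± 0.37). EXPA12, AGP30, an arabinogalactan protein, and PIRL8 had positive values, 2.65 ± 0.48, 2.33 ± 0.37 and 1.97 ± 0.24. Of the glutathione transferases, 8 of 29 were negative, 16 adjusted over the list alone (adjusted p = 2.05e-15, 0.0523 with an estimated correlation). The same direction held for 10 of 16 phenylpropanoid genes, 14 adjusted over the list alone (adjusted p = 7.62e-18, 0.0831 with an estimated correlation), and 8 of 27 sulfate genes, with 1 positive, 16 adjusted over the list alone (adjusted p = 3.03e-06, 0.0523 with an estimated correlation). Aliphatic glucosinolate genes were positive in 8 of 11, 9 adjusted over the list alone (adjusted p = 1.31e-14, 0.065 with an estimated correlation). From the panel, PHT1;1 0.76, APR3 −0.52, GSTU24 −1.33, PAD3 −1.63 and UPOX −1.45 passed, and the other 11 did not (−1.47 to 1.7, adjusted p = 0.081 to 0.78).

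The interaction passed for 579 genes without the 2 libraries, 227 higher and 352 lower, and for 4 as planned, where voom on recovered reads called 0 and limma found 1152 at an unadjusted p under 0.05. The 4, named after their values were seen, are AT5G01740, higher, and UMAMIT36, AT4G01390 and LDOX, lower. Planned splits were 3 and 3 when rescaled and 17 and 16 after quantile normalization. The count was 339 without mock arsenite root 2, 375 without D7 control root 3, 357 without mock control root 2 and 349 without mock control root 3. With 1 library left out, EXPA12, PHT1;1 and APR3 missed the threshold without 1 or more of D7 arsenite 1 and 2, D7 control 1, 2 and 3, mock arsenite 1 and 2 and mock control 2 and 3 (adjusted p up to 0.146). In panel genes it reached 0.146 for PHT1;1 without mock arsenite 1 and 0.1 for APR3 without mock arsenite 2.

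In the fit without the 2 libraries, arsenite changed many of the same root genes with and without the fungus. In plants with D7 and in mock plants, 1401 genes rose in both and 1843 fell in both, where independent lists would share 352 and 442, and 44 passed in opposite directions. These comparisons share no library, and their log2 changes correlated at r = 0.715 across genes, which are not replicates. The effects of D7 in control and in arsenite roots shared 152 rises and 5 falls (CYP71B26, AT3G53830, NYE1, NAC074 and AT5G64170), where independent lists would share 13.2 and 0.5, with 15 opposite and r = 0.267. D7 under arsenite moved 535 genes down that arsenite alone had raised and 560 up that it had lowered, where independent lists would share 117 and 161, and 82 moved the same way in both. This last pair uses the mock arsenite libraries on both sides. Simulated unchanged groups with those shared libraries gave r = 0.599 against the observed 0.596 and a covariance of 0.0174 against 0.114, and shared 0 calls. Part of the excess can come from the shared libraries, which are too few to split.

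**Figure D3:**
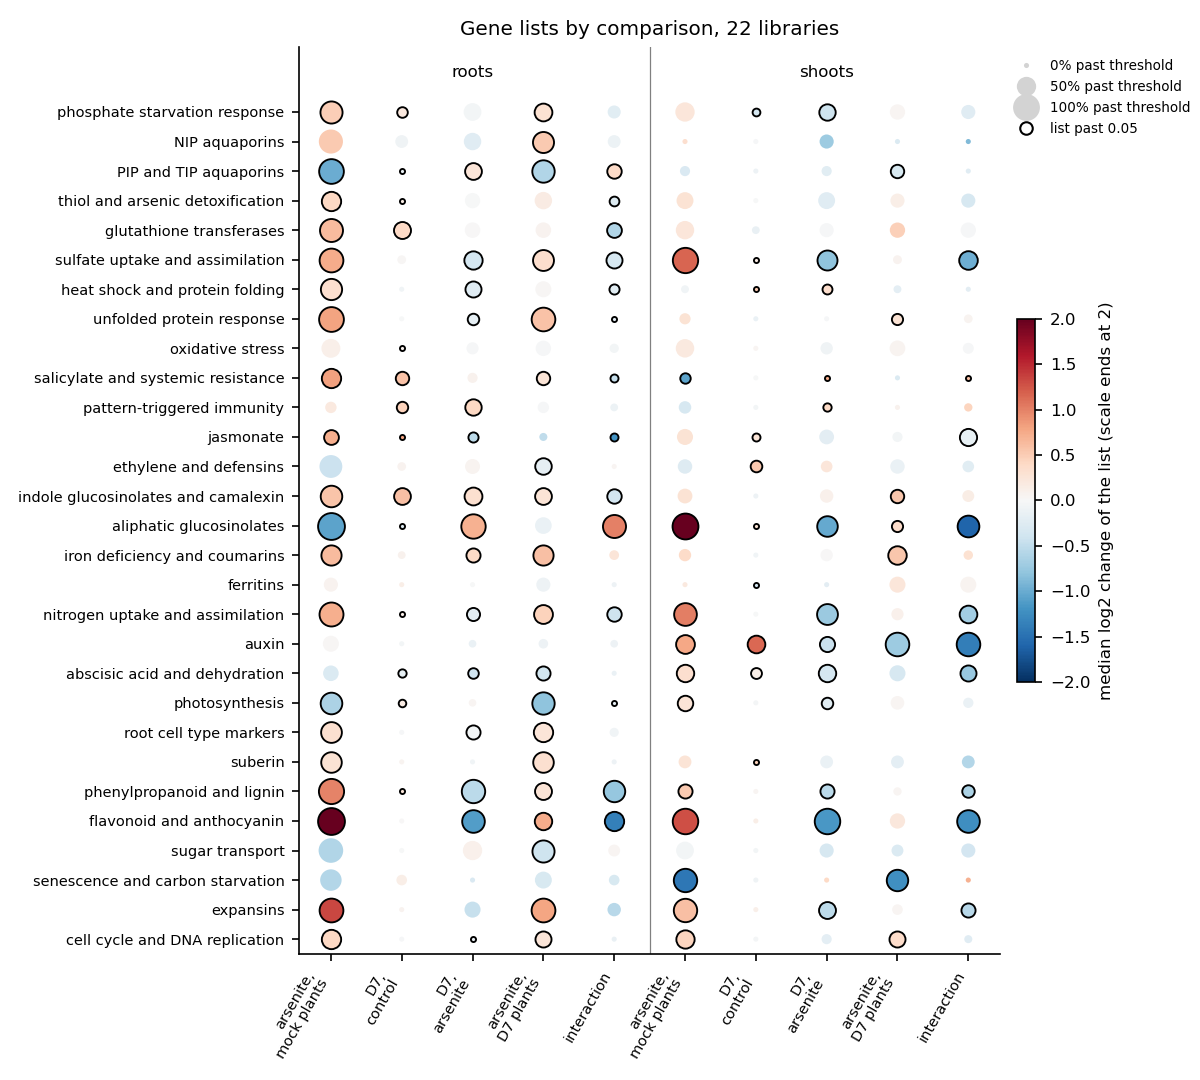
Median log2 change of each gene list in each comparison, as colour, from the fit without the 2 libraries, with size for the share of genes past the threshold and an outline for lists past camera. The aliphatic glucosinolate list has a median of −1.06 in mock roots under arsenite and 2.27 in mock shoots.

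In shoots without the fungus, arsenite raised 9 of 10 flavonoid, 13 of 14 aliphatic glucosinolate and 20 of 26 sulfate genes and lowered 6 of 8 of senescence and carbon starvation. These lists missed the threshold with an estimated correlation (adjusted p = 0.293 to 0.381). DFR, dihydroflavonol reductase, rose from 0.301 ± 0.166 to 13.1 ± 2.33 FPKM (3.43 ± 0.2, adjusted p = 1.4e-05), and GSTF12, needed for anthocyanin transport, rose by 3.4 ± 0.22. IPMI2 and IMD1 of methionine chain elongation rose by 3.31 ± 0.29 and 3.27 ± 0.29, and the glutamine synthetase GLN1;4 from 5.61 ± 1.72 to 62.1 ± 14.2 FPKM (3.27 ± 0.27, adjusted p = 6.2e-05). BCAT-2, a branched-chain aminotransferase, and DIN1, induced by darkness, changed by −3.87 ± 0.39 and −3.74 ± 0.5. The glyoxalase GLYI4, the blue copper protein BCB (AT5G20230) and the nitrate transporter family member NRT2.6 changed by −3.57 ± 0.57, −3.51 ± 0.5 and −3.33 ± 0.62.

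Aliphatic glucosinolate genes (13 up and 0 down of 14, 14 adjusted over the list alone) included, after IMD1, the first committed enzyme CYP79F1 at 3.19 ± 0.47 (adjusted p = 3.42e-10, 0.293 with an estimated correlation). Sulfate genes (20 up and 3 down of 26, 24 adjusted over the list alone) was led by LSU1 3.01 and SDI1 2.85 (adjusted p = 2.1e-07, 0.293 with an estimated correlation). Of the flavonoid and anthocyanin genes, 9 of 10 genes rose and 0 fell, 9 adjusted over the list alone, with LDOX at 2.37 ± 0.26 (adjusted p = 7.14e-07, 0.293 with an estimated correlation). Of the nitrogen genes, 11 of 17 genes rose and 1 fell, 12 adjusted over the list alone, with NRT2.1 2.54 and NIR1 2.38 behind NRT2.6 and GLN1;4 (adjusted p = 1.83e-05, 0.293 with an estimated correlation). Auxin genes (8 up and 0 down of 17, 11 adjusted over the list alone) rose in the flavin monooxygenases YUC9 2.01 and YUC8 1.48 (adjusted p = 1.49e-05, 0.293 with an estimated correlation). Cell cycle genes (8 up and 0 down of 18, 11 adjusted over the list alone) rose in the helicase subunits MCM2 0.93 and MCM7 0.87 (adjusted p = 8.37e-06, 0.293 with an estimated correlation). Senescence genes fell (0 up and 6 down of 8, 6 adjusted over the list alone), with DIN6, an asparagine synthetase, at −2.03 ± 0.58 after DIN1 (adjusted p = 0.000505, 0.381 with an estimated correlation). Photosynthesis genes (7 up and 1 down of 26, 8 adjusted over the list alone) were led by LHCB2.1 1.68 and LHCB1.2 1.45 (adjusted p = 0.0336, 0.754 with an estimated correlation).

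Salicylate genes (0 up and 3 down of 25, 0 adjusted over the list alone) fell in PR2 −3.29 and AED1 −2.65 (adjusted p = 0.000119, 0.754 with an estimated correlation). Abscisic acid genes (5 up and 1 down of 15, 6 adjusted over the list alone) were led by COR15A 2.75 and KIN2 1.41 (adjusted p = 0.0419, 0.457 with an estimated correlation). Phenylpropanoid genes (4 up and 0 down of 16, 5 adjusted over the list alone) were led by PAL3 1.02 and PAL2 0.92 (adjusted p = 0.00364, 0.744 with an estimated correlation) and expansins (5 up and 1 down of 8, 7 adjusted over the list alone) by EXPA15 1.23 and EXPA1 0.94 (adjusted p = 0.00789, 0.437 with an estimated correlation). Lists that did not pass camera were phosphate starvation (8 up and 2 down of 20, 11 adjusted over the list alone, with GDPD1 −2.21 and PHO1;H1 1.54), thiol and arsenic detoxification (3 up and 0 down of 8, 3 adjusted over the list alone, with GGCT2;1 1.4 and ABCC2 0.91), glutathione transferases (5 up and 4 down of 20, 11 adjusted over the list alone, with GSTU20 3.08 and GSTF2 −2.29), and oxidative stress (7 up and 3 down of 22, 10 adjusted over the list alone, with AOX1A 1.26 and RBOHD 1.09). So were pattern-triggered immunity (0 up and 3 down of 16, 0 adjusted over the list alone, with FRK1 −2.28 and WRKY53 −1.78), jasmonate (6 up and 0 down of 18, 7 adjusted over the list alone, with VSP2 2.46 and VSP1 2.41), ethylene and defensins (2 up and 3 down of 19, 6 adjusted over the list alone, with PDF1.2A 1.76 and PDF1.2C 1.26), indole glucosinolates and camalexin (3 up and 2 down of 18, 8 adjusted over the list alone, with PAD3 −2.91 and CYP71A12 −2.21) and sugar transport (3 up and 2 down of 12, 6 adjusted over the list alone, with STP1 −1.79 and SWEET17 1.43). Their camera adjusted p ranged from 0.061 to 0.969.

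From the panel, APR3 rose from 8.88 ± 3.6 to 37.4 ± 4.3 FPKM (2.02 ± 0.29, adjusted p = 0.00085) and PAD3 fell from 12.3 ± 6.48 to 0.623 ± 0.477 FPKM (−2.91 ± 0.79, adjusted p = 0.022), and CHS and UPOX changed by 2.1 ± 0.35 and 0.7 ± 0.14. In the panel 8 did not pass (−3.09 to 1.89, adjusted p = 0.051 to 0.93). HAC1, SULTR1;1 and IRT1 were below the filter in shoots. Here 4511 genes passed without the 2 libraries, 2338 higher and 2173 lower. As planned the count was 2217, 1012 higher and 1205 lower, or 1112 higher and 498 lower when rescaled to a common total. It was 160 as planned with only the groups compared, 2027 without mock arsenite shoot 1 and 1858 without mock arsenite shoot 2. Among named genes, NRT2.1, DIN6, LHCB1.2, PR2, AED1, EXPA1, AOX1A, RBOHD, FRK1, WRKY53, VSP1, PDF1.2A, PDF1.2C, PAD3, CYP71A12, STP1 and UPOX missed the threshold without 1 or more of mock arsenite 1 and 2 and mock control 1, 2 and 3 (adjusted p up to 0.229). Panel genes reached 0.185 for FRK1 without mock arsenite 2, 0.142 for PDF1.2A without mock arsenite 2, 0.14 for PAD3 without mock arsenite 1 and 0.0553 for UPOX without mock arsenite 2. PR2 and AED1 were −4.04 and −3.48 without mock control shoot 1, and VSP1 1.7 without mock control shoot 2.

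In control shoots, D7 raised 7 of 17 auxin genes, 14 adjusted over the list alone (adjusted p = 1.01e-20, 0.0724 with an estimated correlation), and 3 of 19 ethylene and defensin genes, 7 adjusted over the list alone (adjusted p = 4.18e-07, 0.439 with an estimated correlation). FLP1 (AT4G31380) rose from 1.72 ± 0.827 to 33.2 ± 8.74 FPKM (3.66 ± 0.63, adjusted p = 0.031), ST2A (AT5G07010), a sulfotransferase of hydroxyjasmonate, from 6.11 ± 2.36 to 76.1 ± 27.0 FPKM (3.42 ± 0.39, adjusted p = 0.0053), and the ethylene response factor RAP2.6 rose by 3.16 ± 0.38. The ribonuclease RNS1 and the auxin repressor IAA29 rose by 2.95 ± 0.3 and 2.84 ± 0.38. The falls were led by JMJD5, a demethylase of the circadian clock, from 37.2 ± 6.97 to 14.6 ± 0.523 FPKM (−1.28 ± 0.13, adjusted p = 0.0027), and by BT2, BT1, the cold- and clock-regulated COR27 and COL9, with log2 changes of −1.26 ± 0.12, −1.24 ± 0.23, −1.14 ± 0.18 and −0.99 ± 0.1. YUC8, an auxin synthesis enzyme, the ethylene synthesis enzyme ACS8 and the receptor ETR2 rose by 1.91 ± 0.23, 1.68 ± 0.15 and 0.89 ± 0.17.

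From the panel 0 of 15 tested genes passed by limma, at −0.75 to 0.98 and adjusted p of 0.38 to 1. Here 129 genes passed without the 2 libraries, 87 higher and 42 lower. On all libraries the count was 0 by limma and by voom, and 767 had an unadjusted p under 0.05, fewer than chance would give. It was 333 with only the groups compared in either fit, and moved with each library, to 46, 32 and 20 without D7 control shoot 1, 2 and 3, to 60, 43 and 63 without mock control shoot 1, 2 and 3, and to 446 without D7 arsenite shoot 1. When libraries were left out in turn, FLP1, IAA29, BT1, COR27, YUC8 and ETR2 missed the threshold without 1 or more of D7 control 1, 2 and 3 and mock control 1, 2 and 3 (adjusted p up to 0.201).

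In shoots under arsenite, D7 lowered 13 of 26 sulfate, 9 of 10 flavonoid, 8 of 17 nitrogen and 8 of 14 aliphatic glucosinolate genes. With an estimated correlation none of these lists passed (adjusted p = 0.265 to 0.369). The largest rises with all 3 D7 libraries were in NRT2.6, ARCK1 (AT4G11890), a receptor-like kinase, PAD3 and BCB. NRT2.6 rose from 2.35 ± 1.24 to 62.0 ± 61.3 FPKM (3.8 ± 0.62, adjusted p = 0.0041) and PAD3 from 0.623 ± 0.477 to 28.0 ± 30.0 FPKM (3.65 ± 0.79, adjusted p = 0.014), ARCK1 and BCB by 3.68 ± 0.59 and 3.02 ± 0.5, and COR27 from 14.2 ± 5.56 to 93.2 ± 1.89 FPKM (2.68 ± 0.2, adjusted p = 0.00014). GLN1;4 fell from 62.1 ± 14.2 to 7.27 ± 2.16 FPKM (−2.95 ± 0.27, adjusted p = 0.00036), and LSU1 changed by −2.67 ± 0.29. GolS2, a galactinol synthase, CYP79F1 and GSTF12 changed by −2.48 ± 0.36, −2.41 ± 0.47 and −2.4 ± 0.22. The library labelled D7 arsenite shoot 1, with its root marker median of 1.62 FPKM, is 1 of the 3 D7 libraries, and held 62.4 FPKM of PAD3 against 7.04 and 14.6 in the others. Without it the log2 changes were 2.82 for PAD3, 3.02 for NRT2.6, 3.14 for ARCK1 and 2.35 for BCB, and without D7 arsenite shoot 2 4.31 for PAD3 and 4.47 for NRT2.6. GolS2 was −1.85 and −3.1 without mock arsenite shoot 1 and 2.

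Sulfate genes (1 up and 13 down of 26, 20 adjusted over the list alone) was led by LSU1 and SDI1 (−2.05 ± 0.21) (adjusted p = 7.61e-07, 0.265 with an estimated correlation). Of the flavonoid genes, 9 of 10 genes fell and 0 rose, 9 adjusted over the list alone, with DFR at −1.97 ± 0.2 (adjusted p = 7.61e-07, 0.265 with an estimated correlation). Aliphatic glucosinolate genes (0 up and 8 down of 14, 11 adjusted over the list alone) fell in CYP79F1 and MAM3 (−2.34 ± 0.31) (adjusted p = 1.16e-06, 0.369 with an estimated correlation). Nitrogen genes (2 up and 8 down of 17, 14 adjusted over the list alone) fell in NRT2.5 (−2.33 ± 0.27) after GLN1;4 (adjusted p = 3.42e-05, 0.369 with an estimated correlation). Phosphate starvation genes (0 up and 7 down of 20, 9 adjusted over the list alone) were led by PHT1;4 −1.91 and PHO1;H1 −1.55 (adjusted p = 0.000131, 0.265 with an estimated correlation). Auxin genes (0 up and 5 down of 17, 6 adjusted over the list alone) fell in the conjugating enzymes GH3.6 −1.13 and GH3.5 −1.09 (adjusted p = 0.00648, 0.666 with an estimated correlation). Abscisic acid genes (0 up and 6 down of 15, 8 adjusted over the list alone) fell in COR15A −1.32 and RAB18 −1.3 (adjusted p = 0.00704, 0.369 with an estimated correlation). Photosynthesis genes (0 up and 4 down of 26, 4 adjusted over the list alone) fell in LHCB2.1 −2.04 and LHCB2.2 −1.8 (adjusted p = 0.0312, 0.758 with an estimated correlation). Phenylpropanoid genes (0 up and 4 down of 16, 6 adjusted over the list alone) fell in PAL3 −0.99 and PAL2 −0.92 (adjusted p = 0.00127, 0.724 with an estimated correlation) and expansins (0 up and 3 down of 8, 3 adjusted over the list alone) in EXPA1 −1.1 and EXPA8 −1.08 (adjusted p = 0.00292, 0.369 with an estimated correlation).

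Lists that did not pass camera were thiol and arsenic detoxification (0 up and 3 down of 8, 4 adjusted over the list alone, with GGCT2;1 −1.28 and ABCC2 −0.91), glutathione transferases (2 up and 3 down of 20, 7 adjusted over the list alone, with GSTF6 2.34 and GSTF2 1.98), oxidative stress (2 up and 2 down of 22, 4 adjusted over the list alone, with CSD2 1.27 and CAT2 −1.06) and jasmonate (0 up and 5 down of 18, 6 adjusted over the list alone, with VSP1 −2.15 and VSP2 −1.97). Ethylene and defensins (3 up and 0 down of 19, 3 adjusted over the list alone, with PDF1.3 1.65 and ACO1 1.32), indole glucosinolates and camalexin (3 up and 1 down of 18, 4 adjusted over the list alone, with PAD3 and CYP71A12 at 2.44 ± 0.51) and sugar transport (1 up and 2 down of 12, 3 adjusted over the list alone, with SUC2 −1.13 and SWEET10 0.92) also did not. Without D7 arsenite shoot 1, GSTF6 and CYP71A12 were 1.69 and 1.76. Camera adjusted p over these 7 lists ranged from 0.0582 to 0.877. From the panel, ABCC2 fell from 12.8 ± 0.311 to 6.47 ± 1.74 FPKM (−0.91 ± 0.16, adjusted p = 0.0064) and CHS from 20.6 ± 0.495 to 7.09 ± 3.8 FPKM (−1.51 ± 0.35, adjusted p = 0.018). In the panel 12 did not pass (−0.96 to 2.67, adjusted p = 0.066 to 0.98).

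Here 2621 genes passed without the 2 libraries, 1133 higher and 1488 lower. As planned the count was 878, 391 higher and 487 lower, or 81 higher and 284 lower when rescaled to a common total. With only the groups compared it was 486, and as planned 0 by limma, with 2212 at an unadjusted p under 0.05, where voom on all groups called 724. The count was 491 without mock arsenite shoot 1, 711 without mock arsenite shoot 2 and 4297 without D7 arsenite shoot 1. Of the genes above, PAD3, BCB, CYP79F1, GH3.6, GH3.5, COR15A, RAB18, PAL2, EXPA1, EXPA8, GGCT2;1, ABCC2, GSTF6, VSP1, PDF1.3, ACO1, CYP71A12, SUC2, SWEET10 and CHS missed the threshold without 1 or more of D7 arsenite 2 and 3 and mock arsenite 1 and 2 (adjusted p up to 0.294). In the panel it reached 0.119 for PAD3 without mock arsenite 1, 0.0599 for ABCC2 without mock arsenite 2 and 0.121 for CHS without mock arsenite 1.

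Under arsenite in D7-inoculated shoots, auxin genes had 2 up and 11 down of 17, 13 adjusted over the list alone (adjusted p = 0.000361, 0.871 with an estimated correlation). Arsenite raised 5 of 11 iron deficiency genes, 9 adjusted over the list alone (adjusted p = 0.00376, 0.871 with an estimated correlation), and 6 of 18 cell cycle genes, 10 adjusted over the list alone (adjusted p = 0.000174, 0.871 with an estimated correlation). The largest falls were in FLP1, from 33.2 ± 8.74 to 2.67 ± 2.34 FPKM (−3.51 ± 0.63, adjusted p = 0.0057), ST2A, at −3.33 ± 0.39, and XTH15, a xyloglucan endotransglucosylase, at −3.3 ± 0.64. The largest rises were in RL1 (AT4G39250), a MYB-like protein, MES18, a methylesterase, and IMA1, a peptide of iron deficiency, by 2.38 ± 0.36, 2.27 ± 0.34 and 2.07 ± 0.47. The library labelled D7 arsenite shoot 1, with a root marker median of 1.62 FPKM, is in this comparison. FLP1 and XTH15 were −2.74 and −2.6 without D7 arsenite shoot 3, and XTH15 and IMA1 −4.14 and 2.73 without D7 arsenite shoot 1. From the panel UPOX passed (0.57 ± 0.12), and the other 14 did not (−0.39 to 1.49, adjusted p = 0.052 to 0.98). Here 2978 genes passed without the 2 libraries, 1541 higher and 1437 lower. On all libraries the count was 114, 50 higher and 64 lower. It was 1545 with only the groups compared in either fit, 5085 without D7 arsenite shoot 1, 1908 and 1911 without D7 arsenite shoot 2 and 3, and 1790, 1708 and 1292 without D7 control shoot 1, 2 and 3. In fits that left out a library, IMA1 missed the threshold without 1 or more of D7 arsenite 2 and 3 and D7 control 3 (adjusted p up to 0.0615).

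In the interaction in shoots, auxin genes carried the smallest camera p among the 28 lists, as 13 of 17 were negative and 0 positive, 14 adjusted over the list alone (adjusted p = 3.97e-10, 0.247 with an estimated correlation). FLP1 and ST2A had the most negative values, −5.31 ± 0.95 and −4.71 ± 0.59. Without mock arsenite shoot 1 they were −4.32 and −3.95, and without mock arsenite shoot 2 they were −6.31 and −5.48. FLP1 was −4.54 without D7 arsenite shoot 3. Positive values included the clock-associated JMJD5 and COR27 at 3.82 ± 0.2 and 3.82 ± 0.27, and PAD3, NRT2.6 and CYP71A12 at 4.41 ± 1.06, 3.91 ± 0.83 and 3.72 ± 0.69. Without D7 arsenite shoot 1 the last 3 were 3.57, 3.13 and 3.04, below JMJD5 (3.88) and COR27 (3.83), and without D7 arsenite shoot 2 PAD3 and NRT2.6 were 5.06 and 4.58. Aliphatic glucosinolate genes were negative in 9 of 14, 10 adjusted over the list alone (adjusted p = 3.41e-07, 0.408 with an estimated correlation), sulfate genes in 11 of 26 and positive in 1, 21 adjusted over the list alone (adjusted p = 4.06e-07, 0.247 with an estimated correlation), and flavonoid genes in 7 of 10, 9 adjusted over the list alone (adjusted p = 1.93e-06, 0.247 with an estimated correlation). From the panel, ABCC2 −0.77 and CHS −1.85 passed beside PAD3, and the other 12 did not (−1.2 to 3.04, adjusted p = 0.071 to 0.94).

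The interaction passed for 2065 genes without the 2 libraries, 943 higher and 1122 lower, and for 224 as planned, 95 higher and 129 lower. Rescaled to a common total, the splits were 669 higher and 1381 lower, and 20 higher and 95 lower as planned, where quantile normalization gave 38 higher and 89 lower. The count was 3835 without D7 arsenite shoot 1, 542 and 888 without mock arsenite shoot 1 and 2, 1291, 1030 and 1239 without D7 control shoot 1, 2 and 3, and 1125 without mock control shoot 2. In leave-one-out, PAD3, NRT2.6, CYP71A12, ABCC2 and CHS missed the threshold without 1 or more of D7 arsenite 2 and 3, D7 control 1, 2 and 3, mock arsenite 1 and 2 and mock control 1, 2 and 3 (adjusted p up to 0.142). Panel values reached 0.117 for PAD3 without mock arsenite 1, 0.142 for ABCC2 without mock arsenite 1 and 0.119 for CHS without mock arsenite 1.

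In the fit without the 2 libraries, arsenite in shoots with D7 and in mock shoots shared 584 rises and 470 falls, where independent lists would share 196 and 170. In these comparisons, which share no library, 181 genes passed in opposite directions, and r across genes was 0.27. The effects of D7 in control and in arsenite shoots shared 3 rises (GA2OX6, SAUR36 and TRM13) and 6 falls, where independent lists would share 5.4 and 3.4, with 30 opposite and r = −0.201. D7 under arsenite lowered 933 genes that arsenite alone had raised and raised 826 that it had lowered, where independent lists would share 189 and 134, and 11 moved the same way in both. Simulated unchanged groups with the shared mock arsenite libraries gave r = 0.6 against the observed 0.755 and a covariance of 0.0277 against 0.188, with 0 shared calls, and part of the excess can come from the shared libraries.

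**Figure D4:**
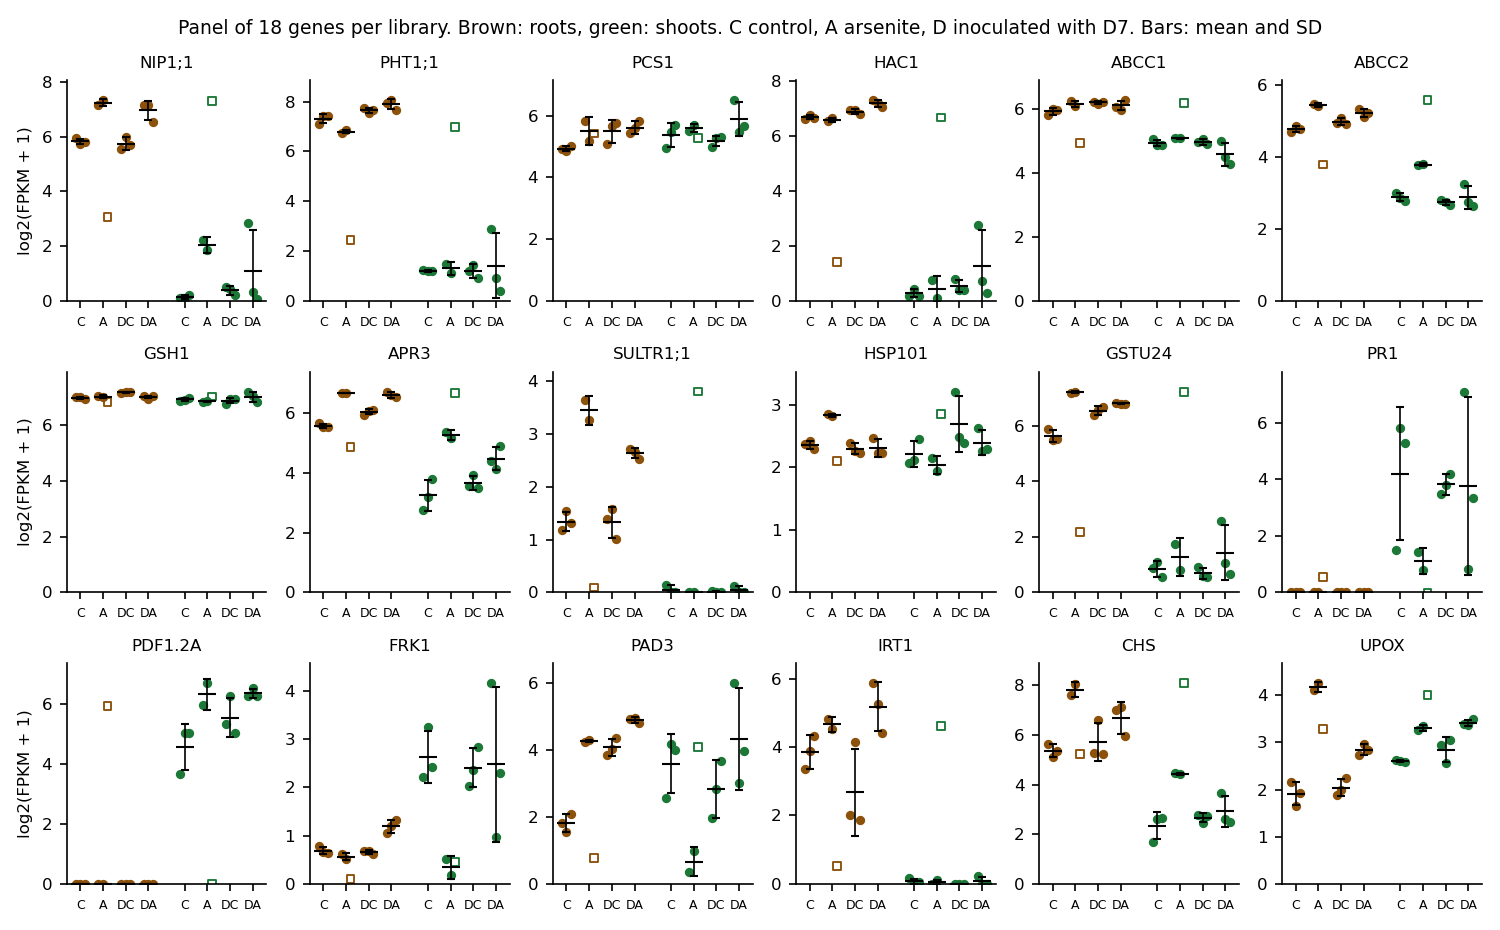
Panel genes as log2(FPKM + 1), 1 point per library, by group in roots (brown) and shoots (green), with bars for mean and SD. PAD3 has 28.0 ± 30.0 FPKM in D7 arsenite shoots.

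Without the 2 libraries, arsenite acted differently on PAD3 and UPOX in roots and shoots of mock plants. The root change minus the shoot change was 5.36 ± 0.87, adjusted p = 0.00061, for PAD3 and 1.57 ± 0.21, adjusted p = 0.00011, for UPOX. The other panel genes tested in both tissues did not pass, at −0.93 to 2.15 and adjusted p of 0.061 to 0.83. Over all genes 2321 genes passed without the 2 libraries, 967 more positive in roots and 1354 in shoots, and 858 as planned, 320 and 538, or 164 and 547 when rescaled to a common total. The count was 1504 without mock arsenite root 1, 1543 without mock arsenite shoot 1 and 1274 without mock arsenite shoot 2. For the effect of D7 in control plants, 0 of the 13 panel genes tested passed by limma, at −0.55 to 3.01 and adjusted p of 0.069 to 1. Over all genes 235 passed without the 2 libraries, 120 and 115, or 94 and 190 when rescaled, and 4 as planned, 2 and 2, or 4 and 11 when rescaled. Chosen after their values were seen, the 4 are NAC042 and CYP81F2, more positive in roots, and PHYB and KIN2, more positive in shoots. The count was 153 without D7 control root 3 or mock control root 1.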

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

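Of the tests below, those of exchanged labels, mixing, depth and the other splits of the samples were chosen only after the results were seen, the measure and spread rule of the clock tests were settled after their values were seen, and the tests of root RNA and of general quality were written before.

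The libraries labelled mock arsenite root 3 and mock arsenite shoot 3 go against their tissue label. An exchange of the 2 labels within the mock arsenite treatment may be the cause. The library labelled root lies nearer to the mock arsenite shoots (mean rho 0.979) than to the D7 arsenite shoots (0.968), and the library labelled shoot nearer to the mock arsenite roots (0.984) than to the D7 arsenite roots (0.978), with a smaller margin of 0.0052. Only a large mixture is argued against, at 2.73% root RNA by 36 root-specific genes in the library labelled root. That labelled shoot would hold 0.05% shoot RNA by 45 shoot-specific genes. A wrong label with a sample outside the series stays open, and no biological explanation was tested.

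The library labelled D7 arsenite shoot 1 holds root marker transcripts. The levels of 36 root-specific genes are consistent with 5.49% root RNA (quartiles 4.75 and 6.04), and all 36 were above both other libraries of the group. A lower depth is argued against, at 1.18 times the mean of the others. A general fall in quality cannot be told apart, since the test of 3863 genes of like level in both tissues, at a ratio of 1.01, was void. The deposited denominators follow median-of-ratios factors within 0.16%, a scaling that holds such a ratio near 1, and a median shows no wider spread between genes. No biological explanation was tested.

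Clock-associated genes such as JMJD5 and COR27 are among the largest shifts in shoots, and 8 evening and 7 morning clock genes were listed. A difference in time of harvest might move such genes. Roots and shoots harvested together, with clocks that run alike, would then shift together, but neither condition is known. Between control groups with and without D7, the evening minus morning difference changed by −0.85 ± 0.13 in shoots and by 0.44 ± 0.09 in roots. On those terms this argues against it as the whole cause. For arsenite without D7 the changes were −1.38 ± 0.26 and 0.23 ± 0.12. Both mock arsenite roots (2.9 and 3.12) lay above the 3 mock control roots (2.71, 2.76 and 2.86). As 0.23 is under 2 standard errors from 0, time of harvest stays open there. With D7 the changes were 1.24 ± 0.18 and 0.06 ± 0.16, and the root change lies within 1 standard error of 0. So time of harvest and, as a hypothesis, an effect of D7 and arsenite on the clock stay open there.

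The effect of D7 depended on arsenite for 4 root and 224 shoot genes on all libraries. Without the 2 these were 579 and 2065, including the root panel genes PHT1;1 (0.76), APR3 (−0.52), GSTU24 (−1.33), PAD3 (−1.63) and UPOX (−1.45). In shoots they were ABCC2 (−0.77), PAD3 (4.41, or 3.57 without D7 arsenite shoot 1) and CHS (−1.85). PHT1;1, APR3, ABCC2, CHS and shoot PAD3 missed the threshold in leave-one-out fits. The effect of arsenite differed between roots and shoots of mock plants for 858 genes on all libraries and 2321 without the 2, with PAD3 at 5.36 and UPOX at 1.57, and that of D7 for 4 and 235.

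Of 100 splits, only the real one gave as many genes for root (4, highest other 2) and shoot interactions (224, highest other 5). The same held for the arsenite tissue difference (858, highest other 6). Splits mix group effects into the spread, so chance stays open. The root count was 1 with a replicate block and 0 by voom, where limma found 1152 at an unadjusted p under 0.05. For the tissue difference of D7, 2 of 100 gave as many as the real 4. The highest other gave 290, which points to a structure whose nature was not tested. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real and highest other counts on all libraries were 2681 and 0 for arsenite in mock roots, 15 and 0 for D7 in control roots, 210 and 1 for D7 in arsenite roots, 3 and 0 for arsenite in D7 roots, 2217 and 0 for arsenite in mock shoots, 878 and 1 for D7 in arsenite shoots and 114 and 0 for arsenite in D7 shoots. For D7 in control shoots all 10 gave 0 by limma and voom called 0. Fewer genes than by chance, 767, had an unadjusted p under 0.05. Without the 2 libraries they were 318 and 0 for D7 in control roots, 4271 and 1 for arsenite in D7 roots, 129 and 0 for D7 in control shoots and 2978 and 0 for arsenite in D7 shoots.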

How the results depend on the processing

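Of the alternatives below, voom, the fits without the 2 libraries that go against their tissue label and the fits also without D7 arsenite shoot 1 were chosen only after the data were seen. On all libraries 117 counts stayed within 1.5 times and 142 moved, and without the 2 libraries 168 and 78. Of values of named genes, on all libraries 5674 kept direction and side of the threshold, 746 lost the threshold, 74 gained it and 10 changed sign, and without the 2 libraries 12094, 1303, 50 and 0. Depth limits low genes, since 3 reads on a 1 kb transcript are 0.101 to 0.195 FPKM. A stricter threshold by itself lowers a count. For the other changes, fewer libraries among them, the cause was not tested.

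On all libraries, counts changed as follows. With a 2-fold minimum they were 700 for arsenite in mock roots, 665 for arsenite in mock shoots, 258 for D7 in arsenite shoots, 53 for arsenite in D7 shoots, 142 for shoot interaction and 512 for tissue difference for arsenite. With rescaling to TPM they were 1781 for arsenite in mock roots, 139 for D7 in arsenite roots, 365 for D7 in arsenite shoots, 115 for shoot interaction and 15 for tissue difference for D7. With quantile normalization they were 39 for D7 in control roots, 318 for D7 in arsenite roots, 33 for root interaction, 1 for D7 in control shoots and 127 for shoot interaction. With a pseudocount of 0.1 FPKM they were 5 for arsenite in D7 roots, 2 for root interaction and 10 for tissue difference for D7. With a pseudocount of 5 FPKM they were 324 for D7 in arsenite roots, 24 for arsenite in D7 roots, 6 for D7 in control shoots and 24 for tissue difference for D7. With no filter they were 10 for arsenite in D7 roots, 1 for D7 in control shoots and 16 for tissue difference for D7. With a filter of 5 FPKM they were 9 for D7 in control roots, 1 for arsenite in D7 roots and 195 for arsenite in D7 shoots. With no trend they were 8 for arsenite in D7 roots. With only the groups compared they were 392 for arsenite in mock roots, 478 for D7 in control roots, 1 for D7 in arsenite roots, 2460 for arsenite in D7 roots, 160 for arsenite in mock shoots, 333 for D7 in control shoots, 0 for D7 in arsenite shoots and 1545 for arsenite in D7 shoots. With a replicate block they were 7 for D7 in control roots, 96 for D7 in arsenite roots, 0 for arsenite in D7 roots, 1 for root interaction, 233 for D7 in arsenite shoots, 17 for arsenite in D7 shoots, 18 for shoot interaction, 545 for tissue difference for arsenite and 0 for tissue difference for D7. By voom on recovered reads they were 14 for arsenite in D7 roots, 0 for root interaction and 67 for arsenite in D7 shoots. At an unadjusted p under 0.05 the root interaction had 1152 genes by limma, little above chance. With only the groups compared D7 in arsenite shoots had 2212 at that p. With a replicate block arsenite in D7 roots had 2727 and the tissue difference for D7 825, fewer than by chance. Leaving out 1 library gave 1001 to 7146 for arsenite in mock roots, 4 to 10 for D7 in control roots, 85 to 1492 for D7 in arsenite roots, 0 to 666 for arsenite in D7 roots, 0 to 579 for root interaction, 1018 to 4511 for arsenite in mock shoots, 0 to 1 for D7 in control shoots, 135 to 2621 for D7 in arsenite shoots, 0 to 363 for arsenite in D7 shoots, 13 to 2065 for shoot interaction, 383 to 1204 for tissue difference for arsenite and 0 to 1 for tissue difference for D7. Without the 2 libraries the counts were 7146 for arsenite in mock roots, 318 for D7 in control roots, 1492 for D7 in arsenite roots, 4271 for arsenite in D7 roots, 579 for root interaction, 4511 for arsenite in mock shoots, 129 for D7 in control shoots, 2621 for D7 in arsenite shoots, 2978 for arsenite in D7 shoots, 2065 for shoot interaction, 2321 for tissue difference for arsenite and 235 for tissue difference for D7.

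Without the 2 libraries, where TPM, quantile normalization, both pseudocounts, a filter of 5 FPKM, no trend and voom moved 0 of these counts by more than 1.5 times, other settings did. Median-of-ratios scaling tests little, as the deposited denominators lie within 0.16% of it. With a 2-fold minimum they were 1126 for arsenite in mock roots, 133 for D7 in control roots, 391 for D7 in arsenite roots, 284 for arsenite in D7 roots, 306 for root interaction, 911 for arsenite in mock shoots, 63 for D7 in control shoots, 519 for D7 in arsenite shoots, 387 for arsenite in D7 shoots, 706 for shoot interaction, 806 for tissue difference for arsenite and 132 for tissue difference for D7. With no filter they were 85 for D7 in control shoots and 356 for tissue difference for D7. With only the groups compared they were 478 for D7 in control roots, 546 for D7 in arsenite roots, 2460 for arsenite in D7 roots, 333 for D7 in control shoots, 486 for D7 in arsenite shoots and 1545 for arsenite in D7 shoots. With a replicate block they were 385 for root interaction, 56 for D7 in control shoots, 1480 for D7 in arsenite shoots and 1175 for shoot interaction. Also without D7 arsenite shoot 1 they were 446 for D7 in control shoots, 4297 for D7 in arsenite shoots, 5085 for arsenite in D7 shoots, 3835 for shoot interaction and 507 for tissue difference for D7. Leaving out 1 library gave 4671 to 6263 for arsenite in mock roots, 175 to 307 for D7 in control roots, 756 to 1651 for D7 in arsenite roots, 1856 to 6138 for arsenite in D7 roots, 339 to 664 for root interaction, 1858 to 3675 for arsenite in mock shoots, 20 to 63 for D7 in control shoots, 491 to 4297 for D7 in arsenite shoots, 1292 to 5085 for arsenite in D7 shoots, 542 to 3835 for shoot interaction, 1274 to 2354 for tissue difference for arsenite and 153 to 250 for tissue difference for D7. Where this leaves mock arsenite with 1 library, that sample is assumed to vary like the other groups.

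Signs changed without the 2 libraries, on the log2 scale, for GSTU24 for root interaction from 0.35 to −1.33 (−1.33 to 1.2 with 1 library left out), GSTU24 for arsenite in mock roots from −0.1 to 1.59 (−0.95 to 1.59 with 1 library left out), SULTR1;1 for D7 in arsenite roots from 0.31 to −0.81 (−0.81 to 0.96 with 1 library left out), APR3 for root interaction from 0.08 to −0.52 (−0.52 to 0.38 with 1 library left out) and PDF1.2A for arsenite in mock shoots from −0.35 to 1.76 (−1.59 to 1.76 with 1 library left out). None of the 5 was past the threshold on all libraries. Of gene lists past camera, 106 on all libraries and 135 without the 2, 0 and 2 passed with an estimated correlation. The 2 were glutathione transferases and indole glucosinolates and camalexin for D7 in control roots. On all libraries shared calls of arsenite with and without D7 went from 2 to 0 in roots with a replicate block, and from 42 to 14 with a 2-fold minimum and 7 with the block in shoots, and those of D7 with and without arsenite in roots from 10 to 4 with the block. Without the 2 libraries a 2-fold minimum left 207 shared calls for arsenite in roots, 105 in shoots, 60 for D7 in roots and 3 in shoots, also 3 with a replicate block. With TPM on all libraries the median of all genes moved from 0.0056 to −0.274 for the tissue difference for arsenite, from 0.0362 to −0.184 and from 0.0315 to 0.174 for the interactions in shoots and roots, from −0.0233 to 0.183 for arsenite in mock shoots and from 0.0323 to −0.143 for D7 in arsenite shoots.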

Other observations

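The values of the clock genes here were chosen only after the largest shifts in shoots had been seen. In shoots the mean log2 difference between evening and morning clock genes was 3.58 (SD 0.18) in mock control, 2.2 (0.34) in mock arsenite, 2.73 (0.13) in D7 control and 3.98 (0.28) in D7 arsenite. In roots it was 2.78 (0.08), 3.01 (0.16), 3.22 (0.14) and 3.29 (0.24). Without the 2 libraries, D7 in arsenite shoots raised 6 and lowered 2 of 8 evening genes and lowered 5 of 6 morning genes. In control shoots D7 lowered 2 evening genes.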
